A study of Mus musculus with 2 samples.

How the data were processed

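Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where HA-tagged Dido3 sat on the genome of mouse embryonic stem cells. Dido3 is a protein isoform made from the Dido1 gene, and HA is a short peptide tag recognised by an antibody. The cells carried an allele labelled Dido3deltaCT and had been given HA-Dido3 back. They were kept in medium with leukemia inhibitory factor (LIF), a cytokine that holds mouse embryonic stem cells in self-renewal. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication, and fragments were precipitated with a polyclonal anti-HA antibody on magnetic beads and made into Illumina libraries. The design held 1 ChIP library and 1 input library of the same cells without antibody, so no comparison has a replicate and no test between conditions could be made.

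The only file was a table of peaks called on the ChIP library. Bowtie, SAMtools, MACS version 1.4 and the genome build mm9 are named in the submitters' processing notes. Read filters, tag extension, the number of sequenced reads and the calling options are not given in the sources used here. Per the file headers, each peak had a start, an end, a length, a summit position, a count of tags, a score, a fold enrichment and a false discovery rate. The tag count is the whole number of ChIP tags in the peak as deposited, with no scaling. The score deposited by the authors is the negative log10 of the peak caller's p-value times 10, and its lowest value lay just above 50, the score of a p-value of 1e-05. The fold enrichment deposited by the authors is the ratio of the ChIP signal at the summit to the background that the peak caller expected there. The false discovery rate was deposited by the authors as a percent, and peak callers of this kind derive it by exchanging ChIP and input. All scores, folds and false discovery rates given below are the authors' own values for each peak, and serve only to describe and rank peaks within this list. Positions are those of the file, counted from 1, in mm9.

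Every row of the table was used (2888 peaks). Peak length equalled end minus start plus 1 in 100% of rows, no row was repeated and no peaks overlapped. The number of peaks called with ChIP and input exchanged, referred to as swapped peaks, was recovered as the false discovery rate times the rank of the peak by score. This product was a whole number, within the rounding of the rate to 0.01 percentage points, for 2809 peaks (97.3%). The other 79 peaks lay within 0.0184 percentage points of the rate that a whole number would give. Fold enrichments were tested for a common step by a grid search. A step of 1.96 was found, of which 2099 folds were whole multiples within 0.01, where smoothly spread values would give 1.02% of peaks by chance. MACS 1.4 divides by the larger of a genome-wide and a local background, so these peaks were taken as having their background at the genome-wide floor, and the remaining 789 as having a local background above it.

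Peaks per chromosome were compared with the share expected from the span between the first and the last peak of each chromosome, because no mm9 chromosome lengths were used here. Intervals are exact Clopper-Pearson intervals at 95% confidence, and intervals of medians are exact binomial intervals. They cover counting error only and treat peaks as independent. Spacing was compared with 1000 seeded random placements of the same peak lengths within the same spans. A region is a run of peaks with gaps of at most 10 kb. The steps were tested on simulated data. Planting 200 close pairs among 2000 randomly placed peaks raised the count of close pairs by 201, since a planted peak can also fall near an unrelated one, and 100% of swapped-peak numbers over 2888 simulated peaks were recovered. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

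Peaks were not assigned to genes, promoters or sequence. The gene table used here describes GRCm38 and coordinates were not converted between builds. That table served only for the number of protein-coding genes per chromosome. The planned shares of peaks at promoters, gene lists, promoter peak scores and base composition were therefore not computed, and the tagged gene itself has no value here. By the rule set before the data were examined, for the case without gene assignment, the peaks named are the 10 with the highest score and the 10 longest. Other peaks, groups and windows are named as the extremes of a stated count and were chosen after their values were seen. Alternatives set before the data were examined were the upper 50% of the list by score, a score of at least 100, autosomes only, leaving out groups of 3 or more peaks, other distances, and an expectation from gene numbers.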

Results

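HA-Dido3 binding was mapped in mouse embryonic stem cells held in self-renewal, with 1 ChIP library set against 1 input library. The question was where on the chromosomes the tagged protein bound. The series held no anti-HA ChIP of cells without the tag. Peaks from the tagged protein and from non-specific precipitation therefore cannot be told apart, and this limit holds wherever binding is named below. The list held 2888 peaks on the 19 autosomes and the X chromosome, which together covered 1.66 Mb. The peaks contained 84288 ChIP tags, while the total number of reads per library is unknown from the table. With no replicate library, all values below describe this 1 peak list, and their intervals cover counting error only.

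Most peaks were short and shallow. The median length was 391.5 bp (95% interval 384 to 400, n = 2888 peaks), and 1913 peaks (66.2%) were shorter than 500 bp. Lengths ranged from 129 bp to 9424 bp, and 325 peaks (11.3%) were longer than 1000 bp. The median peak held 15 tags (interval 14 to 15), with quartiles of 11 and 27 and a range of 9 to 914. Median fold enrichment over the background was 13.7, with quartiles of 11.7 and 17.6, and 418 peaks (14.5%) reached a fold of at least 20. The median score was 75.3 (interval 73.7 to 77.2).

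Swapped peaks gave a background of the list, which counts only an excess of input over ChIP. At the lowest score, 326 swapped peaks stood against the 2888 listed peaks, or 11.3 per 100. Nearly all of them had low scores. Between scores of 50 and 60 there were 894 listed and 200 swapped peaks (22.4 per 100), and between 60 and 75 there were 535 listed and 107 swapped peaks (20 per 100). Between 75 and 100 the ratio was 421 to 10 (2.38 per 100), and between 100 and 200 it was 579 to 3 (0.518 per 100). At scores of 1000 or more, 2 swapped peaks stood against 62 listed peaks. At a score of at least 100, which is a p-value of at most 1e-10, 1038 peaks remained against 9 swapped peaks. The listed false discovery rate exceeded 5% for 1023 peaks (35.4%).

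**Figure D1:**
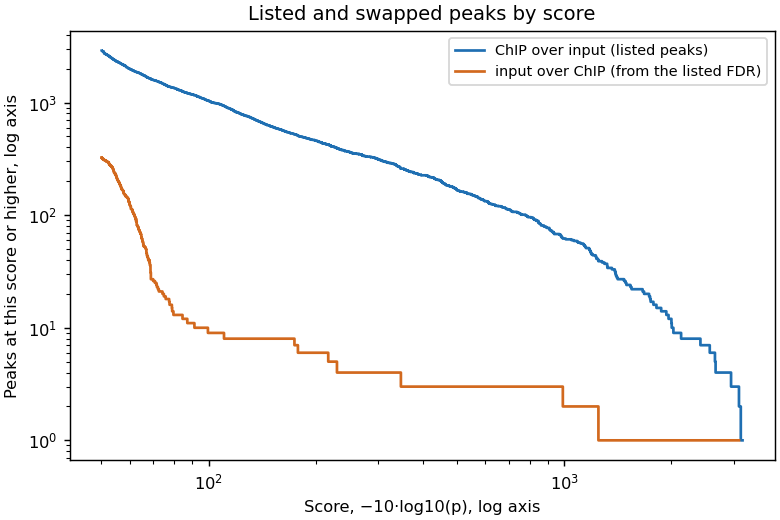
Number of peaks at or above each score (both axes logarithmic) for the listed ChIP peaks and for the swapped peaks recovered from the listed false discovery rate. The lines start at 2888 and 326 peaks, and at a score of 100 stand at 1038 and 9.

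The strongest sites were spread over many chromosomes. The highest score, 3172.42, belonged to a peak of 3748 bp on chromosome 6 (51407508 to 51411255) with 384 tags and a fold of 53. The second, with a score of 3136.91, lay on chromosome 8 (44375136 to 44380258) and had 419 tags and a fold of 45.0. The third lay on chromosome 13 (98256245 to 98265392). Its score was listed as exactly 3100, although its 882 tags and fold of 84.1 exceeded those of both peaks ranked above it. The listed score may therefore understate this peak, and the order of the first 3 ranks cannot be read as their order of strength. Ranks 4 to 8 fell on chromosome 7 (3220164 to 3222674, fold 76.3), chromosome 2 (75506513 to 75509070, fold 64.6), chromosome 9 (7793338 to 7798382, fold 24.2), chromosome 6 (122264789 to 122267818, fold 56.8) and chromosome 9 (78323543 to 78326035, fold 74.4). The last of the 10 highest scores were on chromosome 11 (7907326 to 7910934, fold 36.5) and chromosome 7 (50445346 to 50449024, fold 26.6). Scores of these 10 peaks were 2027.62 or higher. Because 1 swapped peak had a score at least as high as that of rank 3, the listed false discovery rate was 33.33% at rank 3 and fell to 10% at rank 10. These rates depend on the listed order of the first 3 ranks.

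Strong peaks were long, but some of the longest peaks had low folds. The 10 highest scoring peaks were all 2493 bp or longer, against a median of 391.5 bp over the list. Of these 10, 4 were also among the 10 longest. The longest peak, 9424 bp on chromosome 8 (19989533 to 19998956), held 914 tags at a fold of only 9.44. A second peak of that neighbourhood (19787926 to 19792066) had 321 tags, a fold of 4.51 and a score of 59.6. Peaks on chromosome 11 (3031237 to 3035635) and chromosome 4 (146764053 to 146768727 and 146891456 to 146895306) had 450, 468 and 329 tags at folds of 4.57, 7.58 and 6.55. The remaining long peak lay on chromosome 9 (76207295 to 76211523) with 258 tags and a fold of 29.4. Of the 10 longest peaks, 7 had a local background above the genome-wide floor, compared with 27.3% of all peaks (789 of 2888, interval 25.7% to 29.0%). Peaks above the floor had a median fold of 11.8 (interval 11.6 to 11.9), and those at the floor had a median of 15.7 (interval 13.7 to 15.7). A larger background lowers the fold by construction, and the median scores were close, at 76.05 above the floor and 75.26 at the floor.

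**Figure D2:**
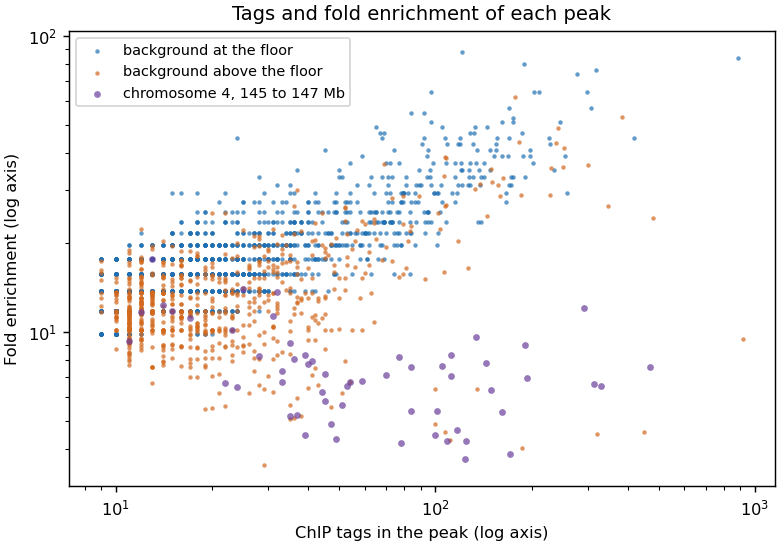
ChIP tags (x axis, logarithmic) and fold enrichment (y axis, logarithmic) of each of the 2888 peaks, coloured by whether the background was at or above the genome-wide floor, with the peaks of chromosome 4 between 145 and 147 Mb marked. The 57 marked peaks have a median fold of 7.07, against 13.7 for the other peaks, and range from 3.7 to 17.6.

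The spread of peaks was uneven between chromosomes. Chromosome 11 held 273 peaks, 1.99 times the number expected from its span (interval 1.77 to 2.23), or 2.30 peaks per Mb. Chromosome 17 held 184 peaks at 1.76 times the expected number (interval 1.52 to 2.02), chromosome 7 held 279 at 1.62 times (interval 1.44 to 1.81), and chromosome 19 held 94 at 1.42 times (interval 1.15 to 1.73). Autosomal densities ranged from 0.775 to 2.30 peaks per Mb. The intervals of 6 chromosomes lay above the expected number, those of 7 below, and those of 7 included it. These intervals treat neighbouring peaks as independent. When peaks within 10 kb were counted as 1 region, an alternative chosen after the data were seen, 5 intervals lay above, 6 below and 9 included it, since those of chromosomes 2 and 18 came to include it. Chromosome 11 stayed at 1.93 times the expected number (interval 1.66 to 2.23).

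The X chromosome had the fewest peaks of the 20 chromosomes. It carried 39 peaks, 0.223 times the number expected from its span (interval 0.159 to 0.304), at 0.257 per Mb. The autosomes together carried 1.21 per Mb. Counted as regions, the X held 28, or 0.251 times the expected number (interval 0.167 to 0.361). Relative to the protein-coding genes of GRCm38, the X had 4.04 peaks per 100 genes (interval 2.87 to 5.52), and the autosomes ranged from 9.99 on chromosome 14 to 17.5 on chromosome 4. The X peaks had a median fold of 15.7 and a median score of 78.5, with 13.7 and 75.3 over the whole list. Of the X peaks, 12.8% had a background above the floor, against 19.4% on chromosome 9, the lowest autosome. Peaks at the floor had a median fold of 15.7 over the whole list as well. The fold of the X peaks therefore does not by itself show stronger enrichment there. The strongest X peak (100677515 to 100680245) ranked 38 in the whole list with a score of 1296.55, 188 tags and a fold of 39.1. The next, at 7713719 to 7714653, ranked 320 with 49 tags.

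**Figure D3:**
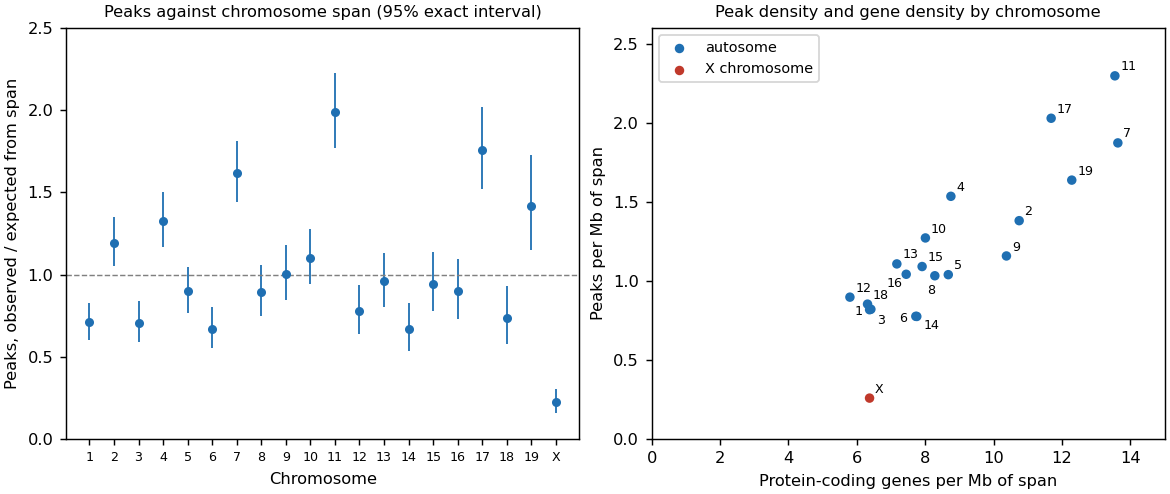
Left, peaks per chromosome divided by the number expected from chromosome span, with exact 95% intervals; right, peaks per Mb against protein-coding genes of GRCm38 per Mb of mm9 span for each chromosome. Chromosome 11 lies at 1.99 and the X at 0.223 of the expected number.

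Expected from gene numbers instead of span, the differences between autosomes were smaller. Chromosome 4 was then highest, at 1.31 times the expected number (interval 1.16 to 1.49). Without its 57 peaks between 145 and 147 Mb, a value chosen after the data were seen, it held 1.01 times (interval 0.872 to 1.17), or 13.3 peaks per 100 genes. Genes of that stretch stayed in the gene number, so these values may be somewhat low. Chromosome 11 held 1.27 times the expected number (interval 1.13 to 1.42), chromosome 17 held 1.30 times (interval 1.12 to 1.496) and chromosome 7 held 1.03 times (interval 0.917 to 1.15). For chromosome 17, the 22 peaks from 15 to 16 Mb, of which 20 had a background above the floor, were not left out in the same way. The intervals of 12 chromosomes included the expected number, those of 4 lay above it and those of 4 below. Counted as regions, 17 intervals included the expected number. Only those of chromosome 11 (1.06 to 1.43) and chromosome 17 (1.04 to 1.499) lay above it, and only that of the X (0.227 to 0.491) lay below. The X was lowest in both counts, at 0.302 times the expected number by peaks (interval 0.215 to 0.412) and 0.341 times by regions.

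Within chromosomes, peaks lay close together. Of all peaks, 58.0% were within 10 kb of another peak, whereas 1000 random placements gave a median of 2.77% and at most 4.22%. Within 1 kb the share was 46.5%, against at most 0.970% in the placements, and within 100 kb it was 75.5%, against at most 26.5%. The median gap to the next peak was 76.1 kb, shorter than in any placement (503.9 to 564.9 kb). Joining peaks within 10 kb gave 1839 regions, of which 1213 held a single peak, 361 a pair and 265 a group of 3 or more. The placements gave at most 5 such groups. Positions in the placements were uniform over each span and ignored gene density and sequence that cannot be mapped. An excess over the placements, also for the windows and gaps below, therefore does not separate clustered binding from an uneven spread of these. Peaks that stood alone had a lower median score (66.1, interval 64.1 to 67.9) than peaks in groups of 3 or more (85.5, interval 81.3 to 91.0). A false discovery rate above 5% was listed for 44.6% of the lone peaks and for 27.3% of the grouped peaks.

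**Figure D4:**
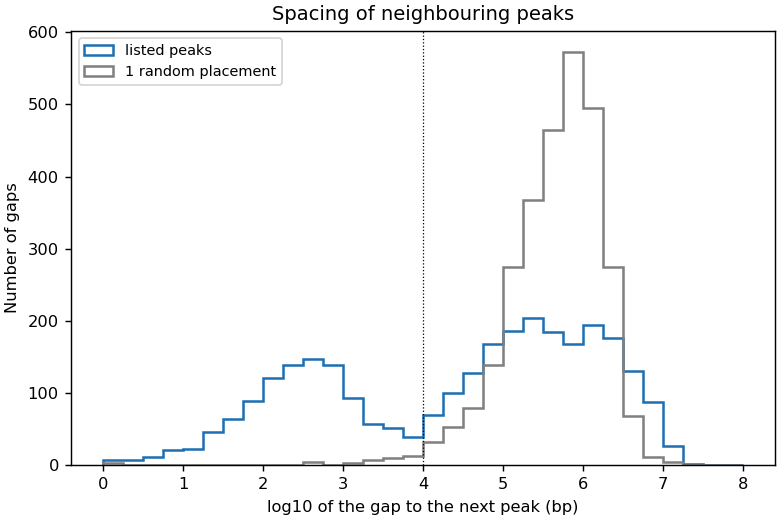
Histogram of the gap from each peak to the next on its chromosome (x axis, log10 of bp; y axis, number of gaps) for the listed peaks and for 1 random placement, with a dotted line at 10 kb; overlapping placed peaks are drawn at the left edge. The listed gaps form 2 humps, and 46.5% of peaks lie within 1 kb of another.

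The largest groups held 9 peaks each. One covered 9.99 kb of chromosome 1 (8936076 to 8946063) with 195 tags, and all 9 of its peaks had a background above the floor. The other covered 5.23 kb of chromosome 2 (157416185 to 157421415) with 212 tags, and 2 of its peaks had such a background. Chromosome 2 also carried a group of 8 (71188057 to 71196968, 277 tags, highest score 746.66) and a group of 7 (180394040 to 180415285, 337 tags, highest score 1226.47), in which 3 and 4 peaks had a background above the floor. Whether this group of 7 lay in the tagged gene, where added HA-Dido3 DNA would raise ChIP and input alike, was not analysed here, so its tags and scores cannot be read as binding alone. A group of 7 on chromosome 7 (150420348 to 150426683) had 121 tags, and all of its peaks had a background above the floor. The peak of rank 3 on chromosome 13 stood in a group of 6 peaks (98256245 to 98269277) with 972 tags in all, none above the floor.

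At the scale of 1 Mb, a few windows held many peaks, though only a minority of the whole list. The most peaks in any window of the random placements was 12. Chromosome 4 held 31 peaks from 146 to 147 Mb and 26 from 145 to 146 Mb, of which 30 and 25 had a background above the floor, with median folds of 6.73 and 7.41. Chromosome 17 held 22 peaks from 15 to 16 Mb, 20 of them above the floor, at a median fold of 10.4. The remaining windows among the 15 taken as having the most peaks had between 0% and 57.1% of them above the floor. Other windows that tied at 14 peaks may have been left out. At the low end, chromosome 10 held 22 peaks from 79 to 80 Mb and 15 from 80 to 81 Mb, none above the floor, at a median fold of 13.7 in both. Chromosome 11 held 21 peaks from 97 to 98 Mb, 2 of them above the floor, and chromosome 7 held 19 from 52 to 53 Mb, 1 of them above the floor. At the high end, 8 of 14 peaks were above it on chromosome 7 from 99 to 100 Mb, 6 of 14 on chromosome 13 from 23 to 24 Mb, and 6 of 15 on chromosome 10 from 127 to 128 Mb. Without the stretch from 145 to 147 Mb and its 57 peaks, chromosome 4 had 1.18 peaks per Mb of the remaining span, down from 1.54.

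Long stretches without a peak were more frequent than in the placements. There were 131 gaps of over 5 Mb, against 15 to 37 in the placements. This is not independent of the close spacing above. The listed peaks formed 1839 regions and the placed peaks 2825 to 2865, and fewer regions over the same span leave longer gaps. The longest, 19.95 Mb on chromosome 16 (64860389 to 84811484), was within the range of the placements, of which 139 of 1000 held one at least as long. Of the 6 longest gaps, 3 were on the X chromosome, at 15.7, 15.4 and 15.3 Mb.

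**Figure D5:**
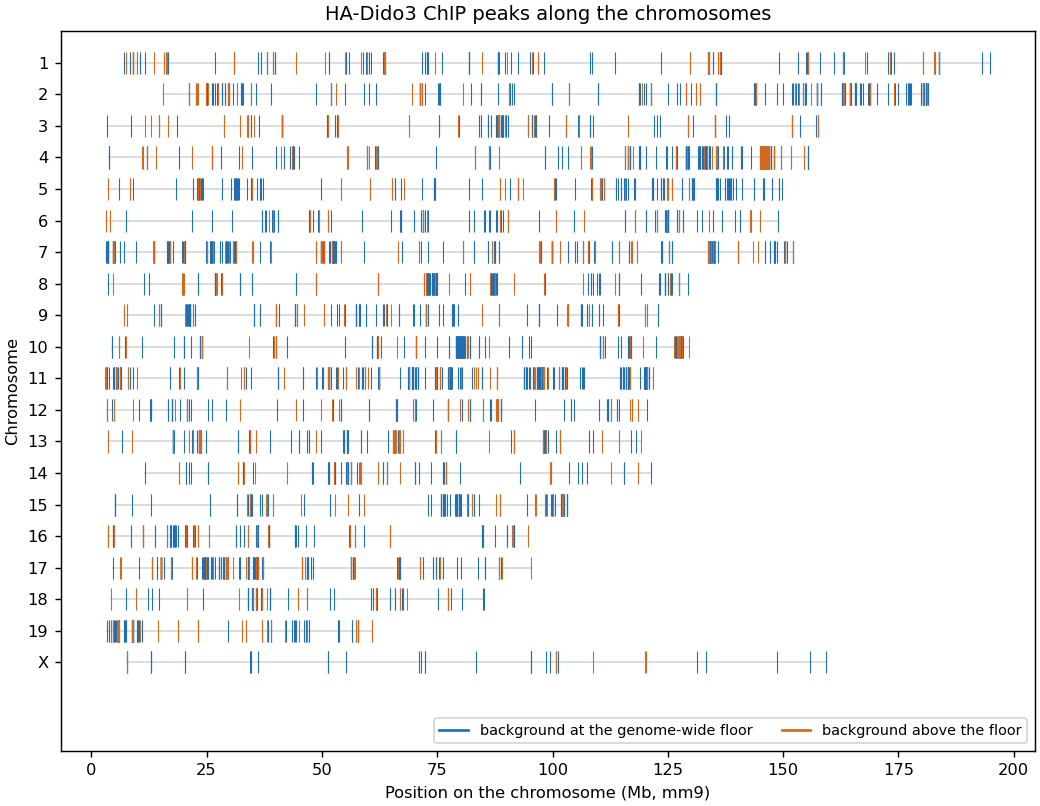
Position of each of the 2888 peaks (vertical bars; x axis, Mb in mm9; y axis, chromosome) along the span from first to last peak, coloured by whether the background was at or above the genome-wide floor. The band of bars above the floor at 145 to 147 Mb of chromosome 4 holds 57 peaks, and the X chromosome holds 39 in all.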

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

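The number of peaks moved from 2888 to 1441 in the upper 50% of the list by score, to 1038 at a score of at least 100, and to 1839 when peaks within 10 kb were counted as 1 region. The medians rose with the stricter scores, which raise the score by construction: in the upper 50% and at a score of at least 100, length was 610 and 721 bp, score 133.6 and 176.2, and fold 17.6 and 19.6, so short and shallow describes the whole list. Without groups of 3 or more peaks, median length was 372 bp and median score 70.9. The share of peaks within 10 kb of another moved from 58.0% to 50.5% in that upper 50%, to 41.5% at a score of at least 100, and to 37.3% without groups of 3 or more peaks. With other distances it was 46.5% at 1 kb and 75.5% at 100 kb. The first 2 of these keep fewer peaks and the third removes close peaks by construction. Each stayed above random placement of the same peaks, the smallest ratio being 3.25 at 100 kb. At 10 kb this ratio was 21.5 for the whole list, 36.35 in the upper 50% and 39.2 at a score of at least 100. Without groups of 3 or more peaks the ratio was 21.2. With stricter scores the share thus fell while the ratio to placement rose. The excess on chromosome 11 moved from 1.99 to 1.27 times when the expected number came from protein-coding genes and to 1.24 times with regions counted as well, and lay between 1.85 and 2.03 under the other alternatives. The deficit on the X moved from 0.223 to 0.341 times with regions and genes together, and stayed between 0.223 and 0.302 times in the other settings that kept the X. No alternative turned a direction. Counting regions, alone or with genes, and leaving out the chromosome 4 windows were chosen after the data were seen. Alternatives for promoters (other distances or any overlap), gene lists (CpG-matched) and base composition were not run, since peaks were not joined to genes or sequence. No paired analysis was possible because there was 1 ChIP library and 1 input library. The lowest tag count was 9 and 159 peaks had it, but how depth limits weak peaks was not tested. Sequencing depth itself is unknown, so absent peaks cannot be read as absent binding.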

Other observations

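The tests of chromosome gene density, of the X chromosome and of the chromosome 4 windows were chosen after the results were seen; so was the test of a larger step. The predictions for a step of 1 tag and for the flanking peaks were written before their results. Gene-rich chromosomes carried more peaks. Across the 20 chromosomes, which are not replicates, peaks per Mb and protein-coding genes per Mb (gene numbers of GRCm38 over mm9 spans) had a Spearman rho of 0.823 (permutation p = 2e-05) and a Pearson r of 0.878 (permutation p = 1e-05, the smallest that 100000 permutations can give). Over the 19 autosomes rho was 0.812 (permutation p = 4e-05) and r was 0.891 (permutation p = 1e-05). Without chromosomes 7 and 11, the farthest in gene density, r was 0.805 (permutation p = 4e-05) and rho was 0.765 (permutation p = 0.00035). The tests are two-sided, and over these 6 p-values the largest Benjamini-Hochberg adjusted value was 0.00035. A candidate explanation is that the tagged protein bound in or near genes. Peak positions joined to an mm9 annotation would test whether the peaks lay there. Without an anti-HA ChIP of untagged cells, non-specific precipitation in or near genes could not be told apart from it.

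The shortfall of peaks on the X chromosome was larger than its gene number accounts for. At 4.04 peaks per 100 protein-coding genes, with an upper limit of 5.52, the X lay below the lowest autosome at 9.99, which argues against fewer genes as the whole cause. A single X copy per cell might also lower tags below the calling limit, and the labels do not give the sex of the line. Autosomal peaks with at least 18 tags, which would keep the lowest count of 9 when divided by 2, predict 55.0 X peaks from gene number, and the observed 39 were 0.709 times that (exact Poisson interval 0.504 to 0.969). From span, 76.0 were predicted and the ratio was 0.513 (interval 0.365 to 0.701). Counted as regions the ratios were 0.694 from gene number (interval 0.461 to 1.00) and 0.502 from span (interval 0.334 to 0.726). Of these 4 intervals, only that of regions from gene number reached 1. The limit of 18 tags treats every peak of 9 tags as called, but 9 was only the lowest count listed. The predicted numbers may therefore be too high, so these ratios cannot decide on a single copy. The shortfall was first to be read as excluding a single copy, but dividing tags by 2 is an assumed profile and nearby peaks are not independent, so a part played by copy number stays open, as does lower binding on the X.

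The 2 adjacent windows on chromosome 4 may be rich in sequence that is over-represented in the input as well. Of their 57 peaks, 96.5% (exact interval 87.9% to 99.6%) had a background above the floor, compared with 25.9% of the other peaks, and their median fold was 7.07 against 13.7. A raised background is what repeated or amplified sequence would give, while each peak still passed the caller's threshold over that background. The lower fold is not separate evidence, since the same background divides it. All peaks above the floor together had a median fold of 11.8. Whether reads that map to several places were kept is not given in the sources used here, so repeated sequence and local binding on it cannot be separated from this table alone. With 1 group of cells, no biological explanation was tested. A raised background was not particular to chromosome 4: from 15 to 16 Mb of chromosome 17, 20 of 22 peaks lay above the floor, at a median fold of 10.4. The windows at 79 to 81 Mb of chromosome 10, with 0 of 37 peaks above the floor, did not share this feature.

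Fold enrichments gave a hint of the depth behind single peaks. If 1 step of 1.96 is 1 tag at the summit, the multiple can never exceed the tags in the peak, and this held for 100% of the 2099 peaks at the floor. That test alone does not set the size of the step. A step of 2 or more tags is argued against by 1088 of these peaks (51.8%), in which 2 times the multiple exceeded the tags. A step smaller than 1 tag was not tested. Under the hypothesis of 1 tag per step these summits rest on a median of 8 overlapping tags, 1404 of them (66.9%) on 5 to 8, so that the presence or absence of a typical peak could turn on a few tags.

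The many peaks within 1 kb of another might have been weak flanks of strong peaks. Of 731 close peaks with a score under 100, 46.9% had a close neighbour with a score of at least 100. Shuffling the scores over the 1343 close peaks gave 45.1% to 55.3% in 1000 draws, with a median of 50.8%. Weak peaks were thus not found next to strong ones more often than in the shufflings. Stretches made only of weak peaks would lower this share, so the test cannot exclude flanks in other stretches. The weak close peaks without such a neighbour were not direct flanks of a peak with a score of at least 100. An enriched stretch divided into pieces of similar score was not tested.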
